A study of Rattus norvegicus with 93 samples.

How the data were processed

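RNA from the healing tissue of 93 calvarial defects was hybridised to 1-colour Agilent whole-genome rat oligonucleotide arrays with Cy3, per the labels' protocols. The labels describe purification on columns, quantification and a check of RNA integrity, and each sample is 1 defect. The deposited values are linear ratios: the median of a probe over the 93 arrays was 1 for 87.8% of 41090 probes, below 1 for the other probes, and the lowest value was 0.01 on each array. Scanner, feature extraction, background correction, scaling between arrays and the reason for the floor are not given in the sources used here. Any scaling of the arrays therefore stays unknown, and signal over background cannot be given. Values at the floor have no order, and a difference that rests on them depends on where the floor lies.

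Samples were put in 14 groups by day and defect size from their titles, and the rat number in the title named the replicate. Symbols came from the platform's annotation: 20932 probes had 1 gene symbol, 0 had several and 20158 were unnamed here. Through RefSeq accessions 17424 probes were matched to current gene names of the GRCr8 assembly, which updated 2316 symbols. Of several probes of a gene the one with the largest interquartile range was used, since most probes are centred on a median of 1, which affected 3880 of 15975 genes; probes of a gene can disagree, and their mean was run as an alternative.

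The design had assumed values on a log scale. As the table held ratios, log2 of the deposited value was taken with no pseudocount. One cell-means model of the 14 groups was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default settings, prior df 1.9), and all adjusted p-values are Benjamini-Hochberg values from its two-sided moderated tests over all genes within a comparison, with a threshold of 0.05. The comparisons were 8 minus 4 mm at each of 7 days and averaged over the days, each later day minus day 1 with both sizes weighted equally, and F tests over the days in each size and of the interaction of size and day. All comparisons with day 1 share its 8 arrays, so their changes are not independent of each other.

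Gene lists were written from general knowledge: bone formation, osteoclast, cartilage, neutrophil, macrophage, inflammatory cytokines, interferon response, T and natural killer cell, B and plasma cell, mast cell, endothelium, hypoxia and glycolysis, cell cycle, fibroblast and wound matrix, matrix proteases and inhibitors, BMP and TGF-beta signalling, Wnt signalling, skeletal muscle, brain, meninges, erythroid and marrow, adipocyte, epidermis, and smooth muscle and pericyte. Of 395 entries in these 24 lists 361 were measured. They were tested with limma's camera with a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison. A list score is the mean log2 value of its measured genes on an array.

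Groups, comparisons, tests, lists, the naming rule and most alternatives were chosen before the data were examined. Named were the 10 genes with the largest increase and the 10 with the largest decrease among those passing, or the 3 with the smallest p where none passed, and list members with large changes. After the data were seen, the ranking by size of change was limited to genes above the floor on every array compared, since differences at the floor have no order.

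Alternatives were quantile normalization, centring of each array, leaving out the less variable genes, the mean of all probes, array weights, the rat number as a block, fits of the compared groups alone, an estimated correlation, and leaving out each array in turn in groups of 3 to 5. Added after the data were seen were raising values under 0.25, testing only the 5413 genes above the floor on all arrays, leaving out the 7 arrays with a level below -0.7 or the 8 with a brain score above 2, and brain and muscle scores as covariates. Tested on simulated data, the code recovered 44.8%, 46.9% and 50% of 8-fold changes for size at days 7, 14 and 21. For day 21 against day 1 this was 59.7%. False calls were 0 to 6.38% of calls. Regrouped real arrays gave medians of 20 and 59 calls for size at days 14 and 21, so simulated rates may not hold for them.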

Results

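Healing of circular holes drilled in the calvaria, the flat roof of the skull, was followed in male rats on 93 one-colour whole-genome arrays. The defects measured 4 or 8 mm across, and the series names the larger a critical-size defect and the smaller a defect below that size. The bone disc was lifted off, the dura mater beneath it was left in place, and the plug of healing tissue was taken out with a trephine of the same diameter at days 1, 3, 5, 7, 10, 14 or 21. The 4 mm groups held 3, 8, 11, 5, 4, 5 and 6 arrays at these days, and the 8 mm groups held 5, 11, 12, 5, 6, 6 and 6. Unoperated bone was not analysed here, so day 1 served as the reference for changes over time. Each sample title gives a rat number. P-values rest on the spread between samples within groups, pooled over all 14 groups. The p-value of a day thus also rests on arrays of other days. The number of arrays limits the precision, and no depth can be given for arrays.

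The deposited values were linear ratios bounded below at 0.01, and 13.4% of them stood at this floor. The median of 12.2% of the probes was below 1, and 45.2% of their values stood at the floor. The median share of values at the floor lay between 10.1% and 10.4% in all groups of days 1, 3 and 5. In 4 and 8 mm defects it was 19.65% and 16.3% at day 14 and 15.7% and 21.2% at day 21. Floor share thus moved with day and size, and counts limited to genes measured above the floor on every array compared are given beside the totals. The median log2 level of the probes never at the floor lay below -0.7 on 7 arrays, which were replicate 13 of 4 mm day 1, replicate 11 of 8 mm day 1, replicates 18 and 20 of 8 mm day 3, replicate 10 of 4 mm day 10 and replicates 10 and 11 of 8 mm day 10. No pair of arrays was identical, and the highest correlation between 2 arrays was 0.618.

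Changes below are log2 differences ± SE from limma, with p-values adjusted over 15975 genes. A count such as 6 of 6 arrays gives the arrays of the later day, or of the 8 mm group, that lay beyond the mean of the other group. Of 63 named differences between sizes on single days that passed, 60 had all arrays beyond that mean, and in 40 of these the groups did not overlap. For changes against day 1 these numbers were 182, 159 and 97. The median change of all genes against day 1 was 0.20, 0.34 and 0.25 at days 3, 5 and 7, and 0.02, 0.01 and -0.05 once each array was centred on its median. At days 10 and 14 it was -0.06 at both and became -0.21 and -0.22 with centring. At day 21 it was -0.18, and -0.20 with centring. Quantile normalization gave 0.06, 0.09, 0.06, -0.12, -0.07 and -0.03 at days 3 to 21. Of the differences between sizes, the median of all genes was -0.16 at day 3, -0.40 at day 7, -0.11 at day 10, 0.14 at day 14 and -0.20 at day 21. With centring these were -0.04, -0.02, -0.00021, 0.06 and -0.03, and quantile normalization gave -0.03, -0.18, -0.04, -0.002 and 0.02. Of 336 list tests with a preset correlation 126 passed, of which 36 also passed with an estimated correlation, and the median of 0 of these 126 changed sign under either scaling.

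Osteocalcin (Bglap), the main non-collagen protein that osteoblasts lay down in bone, rose from a log2 value of -0.68 ± 0.80 (SD, n = 3) at day 1 to 4.49 ± 1.79 (n = 6) at day 21 in 4 mm defects, and from -1.36 ± 1.13 (n = 5) to 6.21 ± 0.81 (n = 6) in 8 mm defects. The neutrophil protein S100a9 ran the other way, from 3.41 ± 0.55 to -2.39 ± 0.91 (n = 11) by day 5 in 4 mm defects and from 3.74 ± 0.45 to -1.87 ± 0.92 (n = 12) in 8 mm defects. Cyclin B1 (Ccnb1), which drives entry into mitosis, was highest at day 3 in 4 mm defects (0.88 ± 0.39, n = 8) and at day 5 in 8 mm defects (0.75 ± 0.48, n = 12), and was lowest in 8 mm defects at day 21 (-2.41 ± 0.42). Over the 7 days together, 5350 genes changed in 4 mm and 6426 in 8 mm defects by limma's moderated F test. Most members of the fibroblast and wound matrix list changed, 14 of 16 in each size, as did 15 and 16 of 18 skeletal muscle genes. Of the bone formation list, 14 of 24 genes changed in 4 mm and 19 of 24 in 8 mm defects, while only 4 of 14 brain genes did in either size. Among the changed genes, the largest share had its highest group mean at day 7 in 4 mm defects (1685 genes, 31.5%) and at day 5 in 8 mm defects (2338 genes, 36.4%). These were also the groups with the highest mean array level of their size (0.44 and 0.13). With each array centred, the largest shares of the same genes were 950 at day 1 (17.76%), ahead of 928 at day 7, in 4 mm and 1477 at day 5 (22.98%) in 8 mm defects. Quantile normalization gave 1228 at day 7 (22.95%) and 1754 at day 5 (27.3%). The difference in peak day was not tested. Limited to genes above the floor on all arrays, 3157 and 3508 genes changed.

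**Figure D1:**
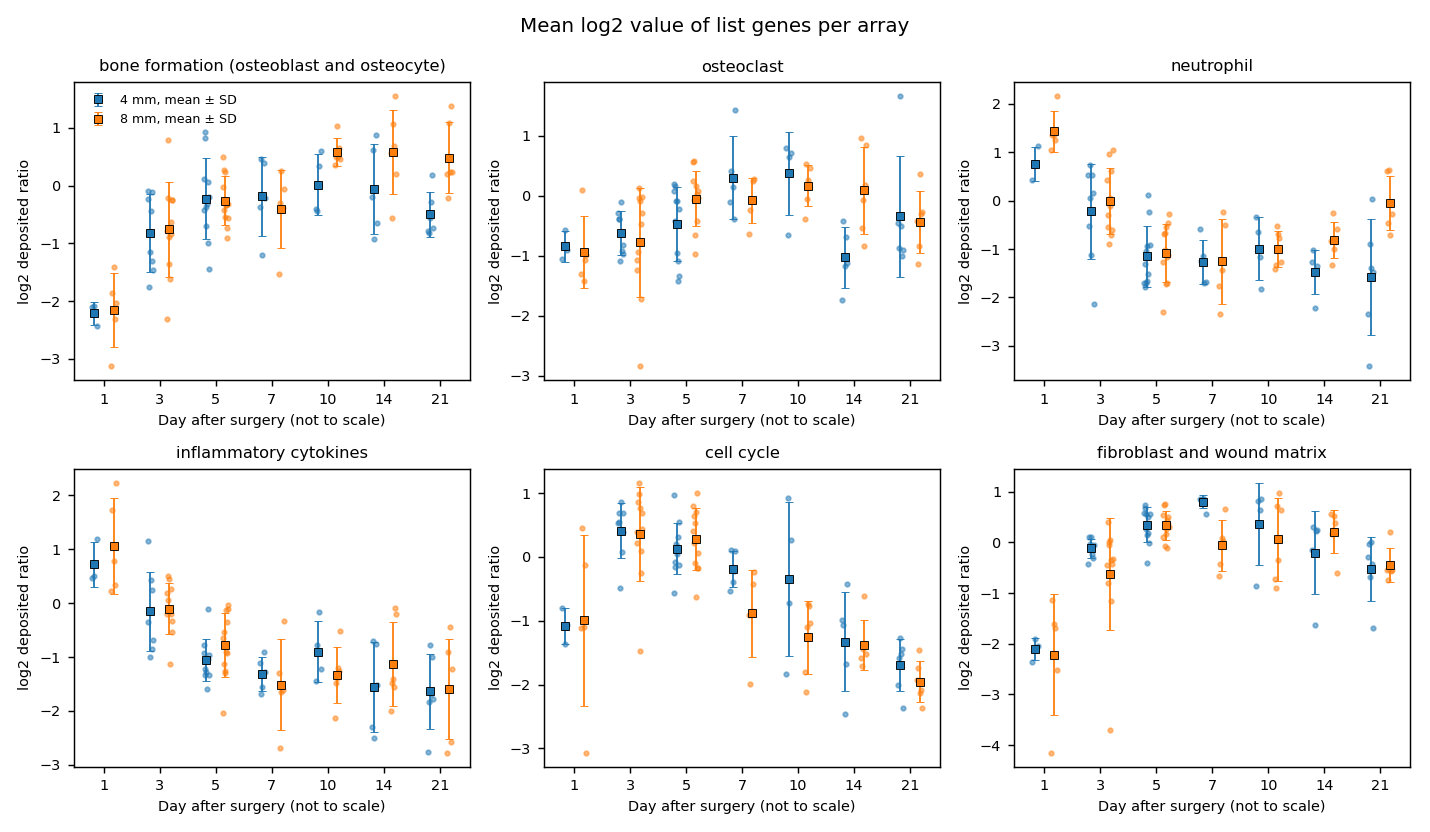
Mean log2 value of the measured genes of 6 lists on each of the 93 arrays against the day of harvest (log2 of the deposited ratio); small points are arrays, large symbols and bars the group mean ± SD, blue for 4 mm and orange for 8 mm defects. The bone formation score rose from -2.21 and -2.15 at day 1 to -0.50 and 0.49 at day 21, and the neutrophil score fell from 0.77 and 1.44 to -1.15 and -1.08 at day 5.

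By day 3 genes of matrix proteins were among those with the largest rises, ranked here and at later days among genes above the floor on all arrays compared. Spon1, a matrix protein also called F-spondin, rose by 3.75 ± 0.30 (higher on 19 of 19 arrays, adjusted p = 3.93e-17), and the small leucine-rich proteoglycan Ogn rose by 3.70 ± 0.30 (19 of 19, adjusted p = 1.14e-16). The other genes with the largest rises were Igsf10, Cdkn1c, Clec2d2, Csrp2, Cxcl13, Sepp1, Srpx2 and Lbp, from 3.08 to 3.58. Among the largest decreases were Hdc, the enzyme that makes histamine (-3.82 ± 0.48, lower on 19 of 19 arrays, adjusted p = 3.51e-09), Stfa2l3 (-3.17 ± 0.59), S100a9 (-2.98 ± 0.44), and Nlrp12, Padi4, Aqp9, Clec4d, Clec4e, Cxcl2 and Chi3l1, from -2.20 to -2.82.
Of the fibroblast and wound matrix list, 12 of 16 rose (13 adjusted over the list alone), among them Col6a1 (2.92 ± 0.33), Col5a1 (2.78 ± 0.35) and Tagln (2.38 ± 0.35). The fibroblast list had adjusted p = 2.89e-22 (adjusted p = 0.0122 with an estimated correlation). Of the cell cycle list 9 of 18 rose (13 adjusted over the list alone), Ccnb1 by 2.64 ± 0.35, Plk1 by 2.40 ± 0.44 and Bub1 by 2.35 ± 0.40. The cell cycle list had adjusted p = 2.61e-10 (adjusted p = 0.0249 with an estimated correlation). In the bone formation list 8 of 24 rose (12 adjusted over the list alone), including Col1a1 (1.93 ± 0.29) and the parathyroid hormone receptor Pth1r (2.10 ± 0.36). The bone formation list had adjusted p = 3.39e-07 (adjusted p = 0.0345 with an estimated correlation). The collagenase-like cathepsin of osteoclasts, Ctsk, rose by 2.52 ± 0.33, yet the osteoclast list did not pass (adjusted p = 0.793).
Neutrophil markers fell in 3 of 16 members (4 adjusted over the list alone). The neutrophil list had adjusted p = 1.39e-06 (adjusted p = 0.00132 with an estimated correlation). Of the inflammatory cytokines 4 of 20 fell (4 adjusted over the list alone), among them Il1b (-1.64 ± 0.37). The cytokine list had adjusted p = 3.39e-07 (adjusted p = 0.0114 with an estimated correlation). The macrophage genes Adgre1 and Trem2 rose by 2.16 ± 0.33 and 1.85 ± 0.30 and Arg1 fell (-1.56 ± 0.37), and the macrophage list did not pass (adjusted p = 0.151). Skeletal muscle genes had a median of -1.21 with 0 of 18 passing, and their list call (adjusted p = 0.000104) was lost with an estimated correlation (adjusted p = 0.281).
In all, 1029 genes changed against day 1 (n = 19 arrays against 8), 954 of them higher, and 857 of the 1029 were above the floor on every array compared. Without replicate 13 of 4 mm day 1 the count was 629, and array weights gave 2490. With the less variable genes left out 7987 were tested and 54 passed. Calls of named genes ended when 1 array was left out (with adjusted p): replicate 17 of 4 mm day 1 that of Cxcl2 (0.0783); replicate 18 of 4 mm day 1 that of Cxcl2 (0.0685); replicate 16 of 8 mm day 1 that of Cxcl2 (0.0782).

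At day 5 Ogn was up by 5.30 ± 0.29 (23 of 23 arrays, adjusted p = 3.73e-26), the cyclin-dependent kinase inhibitor Cdkn1c by 5.38 ± 0.44 (23 of 23) and Mmp12, the elastase of macrophages, by 4.53 ± 0.46 (23 of 23, adjusted p = 4.15e-13). The remaining genes with the largest rises were Igsf10, Srpx2, Clec2d2, Armh4, Mfap4, Mfap2 and Csrp2, from 4.31 to 4.89. S100a9 fell by 5.70 ± 0.43 (23 of 23 arrays lower, adjusted p = 3.82e-19) and the neutrophil-attracting chemokine Cxcl2 at -5.22 ± 0.64 (23 of 23). Padi4, Hdc, Mcemp1, Aqp9, Clec4d, Krt14 and the muscle genes Csrp3 and Ankrd2 fell, from -2.95 to -4.64.
Of the neutrophil list, 7 of 16 fell (8 adjusted over the list alone). The neutrophil list had adjusted p = 1.16e-09 (adjusted p = 2.17e-05 with an estimated correlation). Inflammatory cytokines fell in 9 of 20 members (12 adjusted over the list alone), among them Cxcl2, Ccl20 (-4.37 ± 0.88, at the floor on 1 array) and Cxcl1 (-2.75 ± 0.63). The cytokine list had adjusted p = 5.19e-11 (adjusted p = 0.000477 with an estimated correlation). Epidermal keratins and related genes fell in 3 of 12 members (6 adjusted over the list alone). The epidermis list had adjusted p = 3.67e-05 (adjusted p = 0.0349 with an estimated correlation). Mast cell genes had adjusted p = 0.00247 (adjusted p = 0.0435 with an estimated correlation), and of the members 0 of 9 rose and 1 fell (0 and 1 adjusted over the list alone).
Fibroblast and wound matrix genes rose in 13 of 16 members (14 adjusted over the list alone), Col5a1 by 4.23 ± 0.34 and Postn, a matrix protein of periosteum and scar, by 3.08 ± 0.37. The fibroblast list had adjusted p = 2.18e-19 (adjusted p = 0.024 with an estimated correlation). Of the bone formation list 13 of 24 rose (14 adjusted over the list alone), Col1a1 by 1.76 ± 0.28 and Kazald1 by 4.30 ± 0.34 (at the floor on 1 array). The bone formation list had adjusted p = 3.83e-06 (adjusted p = 0.0456 with an estimated correlation). In the Wnt signalling list 8 of 19 rose (9 adjusted over the list alone), among them Sfrp2 (2.95 ± 0.33) and Fzd1 (2.52 ± 0.35). The Wnt list had adjusted p = 0.00314 (adjusted p = 0.0456 with an estimated correlation). Genes of smooth muscle and pericytes, the cells that wrap vessels, rose in 5 of 12 members (7 adjusted over the list alone), Rgs5 by 3.24 ± 0.31 and Myh11 by 2.76 ± 0.33. The pericyte list had adjusted p = 0.000904 (adjusted p = 0.0435 with an estimated correlation). Endothelial genes rose in 5 of 14 members (6 adjusted over the list alone), among them Kdr (1.86 ± 0.29) and Cldn5 (2.05 ± 0.35), and their call (adjusted p = 0.00691) was lost with an estimated correlation (adjusted p = 0.102).
Of the erythroid and marrow list 4 of 11 fell (10 adjusted over the list alone). The erythroid list had adjusted p = 2.83e-06 (adjusted p = 0.102 with an estimated correlation). Of the adipocyte list 3 of 11 rose and 0 fell (4 and 0 adjusted over the list alone), Fabp4 by 2.05 ± 0.39, and the list did not pass (adjusted p = 0.447). Of the T and natural killer cell list 1 of 14 rose and 1 fell (1 and 0 adjusted over the list alone). The T cell list had adjusted p = 0.00679 (adjusted p = 0.249 with an estimated correlation). Of the B and plasma cell list 1 of 10 rose and 2 fell (1 and 2 adjusted over the list alone). The B cell list had adjusted p = 0.0269 (adjusted p = 0.135 with an estimated correlation).
In all, 3035 genes changed (n = 23 arrays against 8), 2765 of them higher, and 2499 were above the floor throughout. Of 2664 genes passing after centring 2012 were higher, of 3412 after quantile normalization 2511 were, and 1867 genes passed without replicate 13 of 4 mm day 1. When 1 array was left out these calls of named genes ended (with adjusted p): replicate 17 of 4 mm day 1 that of Ankrd2 (0.093) and Csrp3 (0.118); replicate 18 of 4 mm day 1 that of Ankrd2 (0.0576) and Csrp3 (0.0539).

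At day 7 Mmp12 had risen by 5.36 ± 0.53 (10 of 10 arrays, adjusted p = 1.6e-13) and the collagenase Mmp13, made by osteoblasts and hypertrophic chondrocytes, by 4.72 ± 0.55 (10 of 10, adjusted p = 5.73e-11). Above the floor, Spon1 (5.82 ± 0.33) and Itm2a (5.47 ± 0.41) showed the largest rises, and with them Ogn, Cdkn1c, Col16a1, Igsf10, Fcrl2 and Mfap2 rose from 4.91 to 5.29. The muscle genes Myl11 (-5.33 ± 1.30, 9 of 10, adjusted p = 0.00131) and Csrp3 (-5.28 ± 1.33) had the largest decreases above the floor, and Myh1 and Actn3 fell as well (-5.11 ± 1.51 and -4.30 ± 1.20). Hdc fell by 5.27 ± 0.53 (10 of 10), the chemokine Ccl20 at -5.11 ± 1.01 (10 of 10, adjusted p = 5.93e-05), S100a9 at -4.47 ± 0.49, the metal-binding protein Mt2A at -4.39 ± 0.39, Clec4d at -4.00 ± 0.75 and Cxcl2 at -3.94 ± 0.73.
In the list of matrix proteases and inhibitors 8 of 17 rose (8 adjusted over the list alone), with Mmp14 at 2.10 ± 0.31 and Adamts5 at 2.32 ± 0.46; its call (adjusted p = 0.00143) was lost with an estimated correlation (adjusted p = 0.126). Bone formation genes rose in 12 of 24 members (13 adjusted over the list alone), Alpl, the alkaline phosphatase needed for mineralization, by 3.64 ± 0.86. The bone formation list had adjusted p = 7.67e-06 (adjusted p = 0.0582 with an estimated correlation). Of the osteoclast list 5 of 12 rose (6 adjusted over the list alone), Ctsk by 4.39 ± 0.36 and Acp5, the tartrate-resistant acid phosphatase, by 1.49 ± 0.36. The osteoclast list had adjusted p = 0.0226 (adjusted p = 0.268 with an estimated correlation). Fibroblast and wound matrix genes rose in 12 of 16 members (13 adjusted over the list alone). The fibroblast list had adjusted p = 8.56e-16 (adjusted p = 0.0344 with an estimated correlation). Among BMP and TGF-beta signalling genes 8 of 21 rose (9 adjusted over the list alone), Tgfb3 by 3.52 ± 0.42 (at the floor on 1 array). The BMP list had adjusted p = 0.00128 (adjusted p = 0.126 with an estimated correlation).
Skeletal muscle genes fell in 13 of 18 members (17 adjusted over the list alone), Ckm at -7.01 ± 1.57 (at the floor on 2 arrays) and Tnnc2 at -8.29 ± 1.75 (at the floor on 4). The muscle list had adjusted p = 1.5e-11 (adjusted p = 0.0664 with an estimated correlation). The muscle score was 4.05 ± 3.15 (SD, n = 3) and 2.96 ± 2.47 (n = 5) at day 1 in 4 and 8 mm defects and -1.94 ± 0.47 (n = 5) and -0.46 ± 2.21 (n = 5) at day 7. Neutrophil genes fell in 5 of 16 members (6 adjusted over the list alone), with adjusted p = 0.00132 with an estimated correlation. Inflammatory cytokines fell in 11 of 20 members (16 adjusted over the list alone), with adjusted p = 0.00305 with an estimated correlation. Epidermal genes fell in 5 of 12 members (6 adjusted over the list alone), with adjusted p = 0.0344 with an estimated correlation. Hypoxia and glycolysis genes such as Vegfa (-2.62 ± 0.34) and Egln3 (-2.56 ± 0.37) fell in 6 of 16 members (10 adjusted over the list alone), with adjusted p = 3.2e-05 (adjusted p = 0.106 with an estimated correlation), and 1 member, Pfkp, rose by 1.72 ± 0.33.
Genes of the meninges, the membranes between brain and skull, rose in 7 of 12 members (7 adjusted over the list alone), Igf2 by 4.96 ± 0.65 (at the floor on 1 array). The meninges list had adjusted p = 3.93e-05 (adjusted p = 0.0484 with an estimated correlation).
A total of 3419 genes changed (n = 10 arrays against 8), 2646 of them higher, and 2373 were above the floor throughout. Of 3453 genes after centring 2162 were higher and of 3817 after quantile normalization 2542 were, and with the less variable genes left out 597 genes passed, 256 higher.

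At day 10 Bglap had risen by 5.50 ± 0.89 (10 of 10 arrays, adjusted p = 1.52e-06), Alpl by 4.69 ± 0.87 (10 of 10) and Dmp1, a mineralization protein of osteocytes, by 5.02 ± 0.94 (10 of 10, at the floor on 2 arrays). Mmp12 (5.73 ± 0.54), Itm2a, Spon1, Ogn, Mmp13, Cdkn1c, Mfap2, Cxcl13 and Col11a2 made up the other large rises, from 4.91 to 5.73. The muscle gene Myl11 had the largest decrease above the floor (-5.72 ± 1.31, 10 of 10, adjusted p = 0.00083), and the muscle genes Pgam2, Tnni2, Rpl3l and Mb fell, from -3.81 to -4.02. The carbonic anhydrase Car4 fell by 5.07 ± 0.72 (10 of 10, adjusted p = 4.19e-08), as did Hdc (-4.67 ± 0.54), Cxcl2 (-4.58 ± 0.74), Mt2A (-4.16 ± 0.40) and the acute-phase inhibitor Serpina3n (-3.75 ± 0.43).
Of the bone formation list 14 of 24 rose (16 adjusted over the list alone). The bone formation list had adjusted p = 1.3e-13 (adjusted p = 0.00433 with an estimated correlation). Osteoclast genes rose in 5 of 12 members (6 adjusted over the list alone), Ctsk by 4.88 ± 0.37 and Atp6v0d2, a subunit of their proton pump, by 5.87 ± 0.79 (at the floor on 1 array). The osteoclast list had adjusted p = 0.000329 (adjusted p = 0.0674 with an estimated correlation). Of the cartilage list 5 of 14 rose (5 adjusted over the list alone), Col11a2 by 4.91 ± 0.72 and Col9a2 by 2.82 ± 0.56. The cartilage list had adjusted p = 0.0195 (adjusted p = 0.0621 with an estimated correlation). Fibroblast and wound matrix genes rose in 13 of 16 members (14 adjusted over the list alone). The fibroblast list had adjusted p = 3.27e-19 (adjusted p = 0.0188 with an estimated correlation).
Hypoxia and glycolysis genes fell in 9 of 16 members (11 adjusted over the list alone), Slc2a1, the basal glucose transporter, at -1.99 ± 0.36. The hypoxia list had adjusted p = 2.97e-07 (adjusted p = 0.0542 with an estimated correlation). Interferon response genes rose in 5 of 15 members (8 adjusted over the list alone), Irgm by 1.72 ± 0.37 and Gbp2 by 1.72 ± 0.46. The interferon response list had adjusted p = 0.0195 (adjusted p = 0.451 with an estimated correlation). Neutrophil genes fell in 6 of 16 members (9 adjusted over the list alone), with adjusted p = 0.0148 with an estimated correlation. Cytokines fell in 8 of 20 members (12 adjusted over the list alone), with adjusted p = 0.0148 with an estimated correlation. Skeletal muscle genes fell in 16 of 18 members (17 adjusted over the list alone). The muscle list had adjusted p = 1.1e-12 (adjusted p = 0.0592 with an estimated correlation). Of the adipocyte list 2 of 11 rose and 2 fell (3 and 2 adjusted over the list alone), the hormone Lep at -4.21 ± 0.89 (at the floor on 3 arrays), and the list did not pass (adjusted p = 0.61).
Altogether 2651 genes changed (n = 10 arrays against 8), 1668 higher and 983 lower, and 1645 were above the floor throughout. After centring 1725 of 3321 were higher, 1120 genes passed in a fit of the compared groups alone, and 546, 165 of them higher, with the less variable genes left out.

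At day 14 Bglap stood 5.96 ± 0.87 above day 1 (11 of 11 arrays, adjusted p = 7.79e-08) and Alpl 5.21 ± 0.85 (11 of 11). Itm2a showed the largest rise of the genes above the floor, 6.26 ± 0.40 (11 of 11, adjusted p = 1.43e-22), and Ptgds, the prostaglandin D synthase made in meninges and brain, rose by 5.96 ± 1.28 (11 of 11, adjusted p = 0.000238). Ogn, Col11a2, Cdkn1c, Cxcl10, Mmp12 and Ccn3 rose from 5.12 to 5.70. The muscle gene Myl11 had the largest decrease above the floor (-5.58 ± 1.28, 11 of 11, adjusted p = 0.000597), and the muscle genes Mb, Ankrd23 and Tnni2 fell, from -3.79 to -4.42. Among the other genes that fell were Hdc (-5.28 ± 0.52), Ccl20 (-4.46 ± 0.99), both metallothioneins, Mt1 (-4.06 ± 0.31, adjusted p = 2.04e-18) and Mt2A (-4.07 ± 0.39), Serpina3n (-3.91 ± 0.42) and Clec4d (-3.54 ± 0.73).
Bone formation genes rose in 15 of 24 members (17 adjusted over the list alone). The bone formation list had adjusted p = 5.73e-12 (adjusted p = 0.0103 with an estimated correlation). Of the meninges list 6 of 12 rose (6 adjusted over the list alone), with adjusted p = 4.69e-07 and adjusted p = 0.0141 with an estimated correlation, Foxc1, a transcription factor of meninges and skull, by 2.63 ± 0.57. Of the brain list 4 of 14 rose and 0 fell (4 and 0 adjusted over the list alone), the oligodendrocyte gene Mobp by 7.10 ± 1.81 (at the floor on 6 arrays). The brain list had adjusted p = 0.0378 (adjusted p = 0.364 with an estimated correlation). Brain scores were 0.46 ± 2.65 (SD, n = 5) in 4 mm and 0.01 ± 2.23 (n = 6) in 8 mm defects, against -2.29 ± 0.08 (n = 3) and -1.51 ± 1.01 (n = 5) at day 1.
Interferon response genes rose in 8 of 15 members (8 adjusted over the list alone), Cxcl10 by 5.26 ± 0.83 and Irf7 by 2.19 ± 0.55. The interferon response list had adjusted p = 0.000272 (adjusted p = 0.215 with an estimated correlation). Inflammatory cytokines fell in 13 of 20 members (13 adjusted over the list alone), Cxcl2 at -6.52 ± 0.72 (at the floor on 1 array). The cytokine list had adjusted p = 4.8e-07 (adjusted p = 0.0113 with an estimated correlation). Neutrophil genes fell in 7 of 16 members (7 adjusted over the list alone), with adjusted p = 0.0113 with an estimated correlation. Hypoxia and glycolysis genes fell in 11 of 16 members (12 adjusted over the list alone), Ldha, which makes lactate, at -1.79 ± 0.35. The hypoxia list had adjusted p = 3.14e-07 (adjusted p = 0.047 with an estimated correlation). Mast cell genes fell in 4 of 9 members (5 adjusted over the list alone). The mast cell list had adjusted p = 0.00179 (adjusted p = 0.0378 with an estimated correlation). Skeletal muscle genes fell in 14 of 18 members (18 adjusted over the list alone). The muscle list had adjusted p = 1.13e-11 (adjusted p = 0.0599 with an estimated correlation). Of the cell cycle list 1 of 18 rose and 1 fell (1 and 1 adjusted over the list alone), with no list call (adjusted p = 0.882).
In total 3350 genes changed (n = 11 arrays against 8), 2006 higher and 1344 lower, and 1984 were above the floor throughout. The count was 2179 in a fit of the compared groups alone, 2037 over genes never at the floor and 919, 234 higher, with the less variable genes left out; without the low-level arrays 1609 of 3327 were higher.

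By day 21 Bglap had risen by 6.37 ± 0.85 (12 of 12 arrays, adjusted p = 6.63e-09), Ptgds by 6.67 ± 1.25 (12 of 12, adjusted p = 2.17e-05) and Ogn by 5.83 ± 0.33. Itm2a, Mmp12, Cpxm2, Col11a2, the cartilage matrix protein Ucma, Igfbp5 and Cdkn1c rose from 5.16 to 5.77. The muscle genes Myl11 (-5.98 ± 1.25, 12 of 12 lower, adjusted p = 0.000138) and Myh1 (-5.91 ± 1.45) had the largest decreases above the floor, and Tnni2 and Pgam2 fell, from -3.81 to -4.09. Mt2A fell by 4.70 ± 0.38 (12 of 12, adjusted p = 1.97e-17), Mt1 at -4.30 ± 0.31, the leukocyte protease inhibitor Slpi at -4.18 ± 0.40, Hdc at -4.06 ± 0.51, Angptl4 at -3.80 ± 0.44 and the lactate exporter Slc16a3 at -3.77 ± 0.37.
Of the bone formation list 13 of 24 rose (16 adjusted over the list alone), Dlx5, a regulator of osteoblast fate, by 2.83 ± 0.39. The bone formation list had adjusted p = 1.25e-09 (adjusted p = 0.0201 with an estimated correlation). Meninges genes rose in 7 of 12 members (8 adjusted over the list alone). The meninges list had adjusted p = 9.72e-07 (adjusted p = 0.0239 with an estimated correlation). Of the brain genes 4 of 14 rose and 0 fell (4 and 0 adjusted over the list alone), Mbp, a myelin protein, at 2.77 ± 0.94. The brain list had adjusted p = 0.0148 (adjusted p = 0.258 with an estimated correlation). Leaving out 1 array ended calls of named genes (with adjusted p): replicate 17 of 4 mm day 1 that of Mbp (0.058). The 4 mm arrays of day 21 had a brain score of 2.08 ± 3.02 (SD, n = 6) and the 8 mm arrays one of -1.41 ± 0.84 (n = 6). Genes of BMP and TGF-beta signalling changed in both directions: 11 of 21 rose and 2 fell (12 and 3 adjusted over the list alone), Gdf10 by 6.47 ± 0.59 (at the floor on 2 arrays). The BMP list had adjusted p = 0.000319 (adjusted p = 0.101 with an estimated correlation).
T and natural killer cell genes rose in 7 of 14 members (8 adjusted over the list alone), Cd3g by 2.05 ± 0.34 and Prf1 by 1.77 ± 0.35. The T cell list had adjusted p = 0.000473 (adjusted p = 0.168 with an estimated correlation). Macrophage genes fell in 6 of 16 members (7 adjusted over the list alone), the scavenger receptor Msr1 at -4.01 ± 0.45 (at the floor on 1 array) and Arg1 at -2.92 ± 0.40, while Adgre1 rose by 1.98 ± 0.35. The macrophage list had adjusted p = 0.00187 (adjusted p = 0.258 with an estimated correlation). Erythroid and marrow genes rose in 9 of 11 members (9 adjusted over the list alone). The erythroid list had adjusted p = 0.00159 (adjusted p = 0.258 with an estimated correlation). Cytokines fell in 12 of 20 members (13 adjusted over the list alone), Il6 at -4.24 ± 0.52 (at the floor on 2 arrays). The cytokine list had adjusted p = 2.43e-07 (adjusted p = 0.0201 with an estimated correlation). Skeletal muscle genes fell in 17 of 18 members (18 adjusted over the list alone), Ckm at -9.76 ± 1.51 (at the floor on 6 arrays). The muscle list had adjusted p = 1.98e-10 (adjusted p = 0.0942 with an estimated correlation).
Of 4190 genes that changed (n = 12 arrays against 8) 2144 were higher and 2046 lower, and 2406 were above the floor throughout, 1734 of them higher. The count was 2365 over genes never at the floor and 1202, 332 higher, with the less variable genes left out. Those higher were 2218 of 4861 with array weights and 1828 of 4451 without the low-level arrays. They were 1737 of 3532 with the rat number as a block, though numbers recurring on other days mark other defects.

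**Figure D2:**
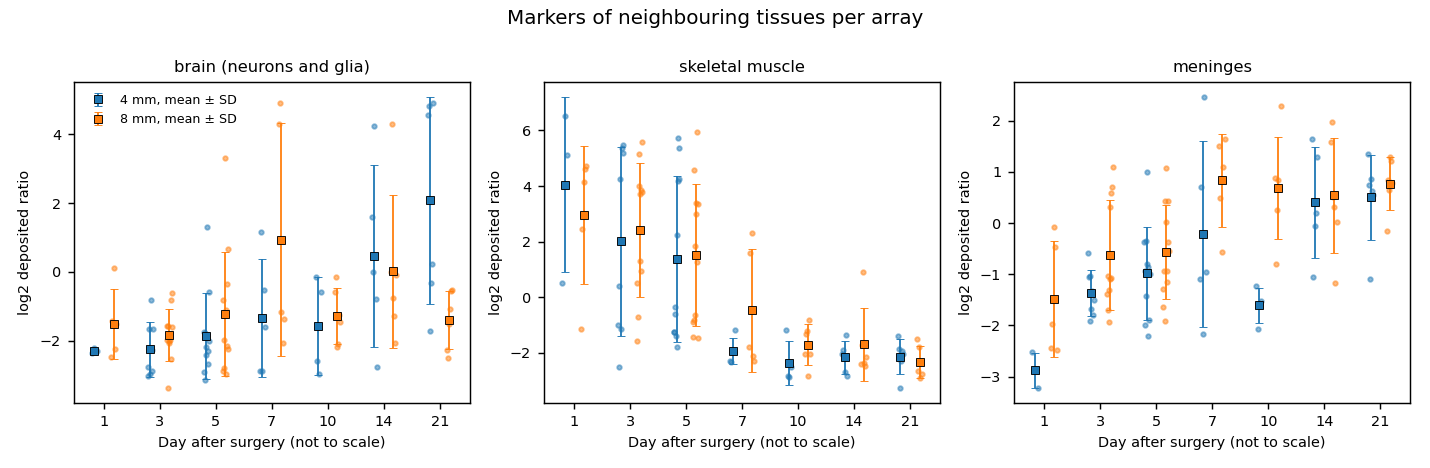
Mean log2 value of the brain, skeletal muscle and meninges genes on each of the 93 arrays by day (log2 of the deposited ratio); blue points are 4 mm and orange points 8 mm defects, offset sideways, and bars the group mean ± SD. Muscle scores of days 1 to 5 reach from -2.50 to 6.53, and brain scores of 4 mm defects at day 21 from -1.73 to 4.92.

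The comparison of 8 with 4 mm defects asked what distinguishes a critical-size defect from a smaller defect at each day. At day 1, limma called 0 genes (n = 5 against 3); 421 passed an unadjusted p of 0.05 and the smallest adjusted p was 0.146, for Stxbp4 (2.93 ± 0.62, higher on 5 of 5 arrays). Dkk3 differed by 3.33 ± 0.82 and Wnt2b by 4.54 ± 1.10, with adjusted p = 0.589 and 0.589. Meninges genes were higher (median 1.08, 0 of 12 passing, 0 adjusted over the list alone) and epidermal genes lower (median -1.45, 0 of 12 passing), and skeletal muscle (median -0.99) and smooth muscle genes (median -0.58) were lower too. These 4 list calls had adjusted p = 0.0102, 0.0102, 0.0102 and 0.0311, and with an estimated correlation adjusted p = 0.476, 0.476, 0.801 and 0.476. Other settings called 37 genes (array weights), 21 (the compared groups alone), 4 (without the low-level arrays), 2 (quantile normalization), 3 without replicate 13, 17 or 18 of 4 mm day 1 and 2 without replicate 16 of 8 mm day 1. In simulated data 24.2% of genes changed 8-fold were recovered at this sample size.

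Erythroid and marrow genes were higher in 8 mm defects at day 3, with a median of 1.09, among them the red cell anion exchanger Slc4a1 (1.87 ± 0.75) and the haemoglobin chaperone Ahsp (1.77 ± 0.58). Of these genes 0 of 11 passed over all genes and 1 adjusted over the list alone. Fibroblast and wound matrix genes were lower, with a median of -0.48 and 0 of 16 passing. The list calls were adjusted p = 1.25e-08 and adjusted p = 4.97e-05, and with an estimated correlation adjusted p = 0.313 and 0.83. A meninges call (adjusted p = 0.0373) was likewise lost (adjusted p = 0.83 with an estimated correlation). By gene, limma called 0 (n = 11 against 8), with 485 at an unadjusted p of 0.05. Tekt2 had the smallest adjusted p (2.57 ± 0.57, adjusted p = 0.296, 11 of 11, 6 of them above every 4 mm array), and Amy2-3 (1.93 ± 0.52) and Rnls (-5.55 ± 1.46, at the floor on 7 arrays) had adjusted p = 1 and 1. Array weights called 4 genes and quantile normalization 2.

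The erythroid and marrow genes were again higher at day 5, with a median of 1.27 and 8 of 11 passing adjusted over the list alone against 0 over all genes, among them Slc4a1 (2.10 ± 0.67), Epb42 (1.67 ± 0.53) and Rhd (1.73 ± 0.59). Their list call was adjusted p = 1.05e-12, and adjusted p = 0.0668 with an estimated correlation. Interferon response genes (median 0.35, Rsad2 1.62 ± 0.54), BMP and TGF-beta signalling genes (median 0.22, Bmp6 2.56 ± 0.74) and adipocyte genes (median 0.59, Adipoq 1.85 ± 0.63) were higher and epidermal genes lower (median -0.31), with 0 members passing over all genes and 0, 1, 1 and 0 adjusted over the list alone. These lists had adjusted p = 0.0122, 0.0429, 0.014 and 0.0331, and with an estimated correlation adjusted p = 0.892, 0.892, 0.623 and 0.623. By gene, limma called 0 (n = 12 against 11), with 474 at an unadjusted p of 0.05. Rpl37 (-1.03 ± 0.24, lower on 12 of 12, 10 of them below every 4 mm array) and Ptms (-1.06 ± 0.26, 12 of 12, 8 of them below every 4 mm array) had adjusted p = 0.833 and 0.833, and Hhip differed by -4.93 ± 1.27 (adjusted p = 1, at the floor on 10 arrays). Quantile normalization called 63 genes, 3 of them higher, array weights 20, and centring and leaving out the low-level arrays 1 each.

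In 8 mm defects at day 7, Hrct1 was lower, at -2.98 ± 0.55 (5 of 5 arrays, adjusted p = 0.00695), the deubiquitinase Usp47 at -2.54 ± 0.50 (5 of 5, adjusted p = 0.00724) and Polr2j, a subunit of RNA polymerase II, at -2.77 ± 0.55 (5 of 5). Rpl36al1 (-3.07 ± 0.65) and Tmem223 (-3.12 ± 0.65) were lower as well, as were Acot11, Calu, B9d2 and Slc30a5, from -2.50 to -2.91, and Ccdc93 (adjusted p = 0.0164). Above the floor only B4galnt1 was higher (1.87 ± 0.48). Fibroblast and wound matrix genes had a median of -0.85 with 0 of 16 passing, and macrophage genes a median of -0.82 with 1 of 16 passing (1 adjusted over the list alone). Brain genes were higher by a median of 2.46 and skeletal muscle genes by 1.63, with 0 of 14 and 0 of 18 passing, and erythroid genes, 0 of 11 passing, by 1.21. The lists had adjusted p = 0.00207, 0.0303, 0.000342, 0.00207 and 0.00228, and with an estimated correlation adjusted p = 0.727, 0.727, 0.345, 0.727 and 0.727. Brain scores of the 8 mm arrays at this day ran from -2.06 to 4.92 (0.93 ± 3.39, SD, n = 5).
Limma called 59 genes, 9 higher and 50 lower (n = 5 against 5), of which 34 were above the floor on all arrays compared, 1 of them higher. After centring 28 of 69 were higher and after quantile normalization 18 of 69. Without replicate 13 of 8 mm day 7 only 2 genes passed. Among the named genes, leaving out 1 array ended these calls (with adjusted p): 4 mm replicate 10 that of Calu (0.0899) and Slc30a5 (0.0502); 4 mm replicate 12 that of B9d2 (0.0526), Calu (0.118) and Slc30a5 (0.0592); 4 mm replicate 13 that of B4galnt1 (0.187); 4 mm replicate 14 that of B9d2 (0.0521), Calu (0.1) and Slc30a5 (0.0521); 4 mm replicate 15 that of B4galnt1 (0.231), Calu (0.104) and Slc30a5 (0.0602); 8 mm replicate 10 that of B4galnt1 (0.0787); 8 mm replicate 12 that of B4galnt1 (0.0512); 8 mm replicate 13 that of Acot11 (0.259), B4galnt1 (0.0686), B9d2 (0.188), Calu (0.188), Ccdc93 (0.259), Polr2j (0.213), Rpl36al1 (0.259), Slc30a5 (0.306), Tmem223 (0.259) and Usp47 (0.0736); 8 mm replicate 14 that of Acot11 (0.0712), B4galnt1 (0.0885) and Calu (0.105); 8 mm replicate 15 that of B4galnt1 (0.067), B9d2 (0.0565), Calu (0.127) and Slc30a5 (0.112). Without the arrays high in brain markers the call of B4galnt1 (0.11) ended. The count was 158, 128 and 123 without replicates 12, 10 and 15 of 8 mm day 7, and 27, 26, 34 and 39 without replicates 10, 12, 14 and 15 of 4 mm day 7. A fit of the compared groups alone called 6 genes, 6 higher and 0 lower, and shared 0 with the 59. With the rat number as a block 4 passed, 2 higher and 2 lower, of which 3 were shared. Over all settings the counts ran from 1 with the less variable genes left out to 2106 with array weights.

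At day 10 Slc5a6, a transporter of biotin and pantothenate, was higher in 8 mm defects by 2.28 ± 0.40 (6 of 6 arrays, adjusted p = 0.00062), Eya2 by 2.35 ± 0.45 (6 of 6, adjusted p = 0.00267), Cdk18 by 2.27 ± 0.43 (6 of 6) and the cartilage collagen gene Col9a2 by 3.49 ± 0.74 (6 of 6, adjusted p = 0.0101). The largest difference above the floor was that of Igfbp2 (5.12 ± 1.25, 6 of 6, adjusted p = 0.0375), and Gjb2, Ghrh and Slc4a4 were higher, from 2.63 to 4.15. Of the meninges list 3 of 12 passed (4 adjusted over the list alone), the transcription factor genes Foxc2 (4.66 ± 0.82, at the floor on 1 array), Zic1 (4.38 ± 1.04, at the floor on 2) and Foxc1 (3.21 ± 0.77). The meninges list had adjusted p = 4.5e-08 (adjusted p = 0.0161 with an estimated correlation). BMP and TGF-beta signalling genes had a median of 0.62 with 0 of 21 passing and 3 adjusted over the list alone, and adjusted p = 0.000178 (adjusted p = 0.175 with an estimated correlation). Of cartilage genes 2 of 14 passed (2 adjusted over the list alone), Col9a2 and Epyc (4.24 ± 1.01). The cartilage list had adjusted p = 0.0601 (adjusted p = 0.175 with an estimated correlation). The meninges score was 0.69 ± 1.00 (SD, n = 6) in 8 mm and -1.61 ± 0.34 (n = 4) in 4 mm defects.
Limma called 42 genes, 40 of them higher (n = 6 against 4), and 17, all higher, were above the floor throughout; 65 passed after centring and 12 after quantile normalization. With the rat number as a block 65 passed, 36 higher and 29 lower, and 17 were shared with the 42. The compared groups alone gave 8, 6 higher, with 1 shared, and without the low-level arrays 41 passed, 32 higher, with 18 shared. Without replicate 13 of 4 mm day 10 the count was 72. Named genes lost their call (with adjusted p) when 1 array was left out: 4 mm replicate 10 that of Epyc (0.0598), Foxc1 (0.0598), Igfbp2 (0.053), Slc4a4 (0.102) and Zic1 (0.166); 4 mm replicate 11 that of Epyc (0.0628), Ghrh (0.154), Gjb2 (0.0891), Igfbp2 (0.0572) and Slc4a4 (0.0914); 4 mm replicate 12 that of Epyc (0.0966), Foxc1 (0.276), Foxc2 (0.0506), Ghrh (0.136), Igfbp2 (0.185), Slc4a4 (0.0507) and Zic1 (0.213). Leaving out the low-level arrays ended the calls of Epyc (0.0796), Foxc1 (0.0613), Igfbp2 (0.0601), Slc4a4 (0.0796) and Zic1 (0.2).

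At day 14 Slc10a6 was higher in 8 mm defects by 2.75 ± 0.53 (6 of 6 arrays, adjusted p = 0.00122) and complement factor I (Cfi) by 2.30 ± 0.47 (6 of 6, adjusted p = 0.00212). Epas1 was higher by 2.84 ± 0.55 (6 of 6, 1 of them above every 4 mm array, 4 mm replicates 16 to 18 at -3.42 to -5.27, adjusted p = 0.0011). The haemoglobin scavenger receptor of macrophages, Cd163, was higher by 4.20 ± 0.78 (6 of 6, at the floor on 1 array) and the iron-binding neutrophil protein Lcn2 by 4.32 ± 0.87 (6 of 6, at the floor on 2 arrays). Above the floor Zxdc, Cadm4, Folr1, St6galnac2, Klf9 and Ptgis were also higher, from 2.11 to 2.61. Slfn4 was lower, at -3.02 ± 0.72 (6 of 6, 3 of them below every 4 mm array, adjusted p = 0.0112), as were Gpd1l1, Tmem88 and Sds, from -1.13 to -1.25. Each of Cd163, Lcn2, Mmp9 (2.33 ± 0.57) and Eng (2.27 ± 0.63) was the only gene of its list to pass. The macrophage, neutrophil, osteoclast and endothelium lists had adjusted p = 0.42, 0.64, 0.152 and 0.715. Interferon response genes were lower, with a median of -0.93 with 0 of 15 passing. The interferon response list had adjusted p = 3.46e-05 (adjusted p = 0.698 with an estimated correlation). Of BMP and TGF-beta signalling genes 2 of 21 passed (2 adjusted over the list alone). The BMP list had adjusted p = 0.00281 (adjusted p = 0.698 with an estimated correlation).
Limma called 261 genes, 243 of them higher (n = 6 against 5), of which 56, 52 of them higher, were above the floor throughout. Without replicate 17 of 4 mm day 14 the count was 89, without replicates 16 and 20 it was 398 and 394. Of the named genes, single arrays left out ended the following calls (with adjusted p): 4 mm replicate 15 that of Sds (0.0793); 4 mm replicate 16 that of Gpd1l1 (0.0751) and Sds (0.139); 4 mm replicate 17 that of Eng (0.488), Folr1 (0.106), Gpd1l1 (0.164), Klf9 (0.199), Mmp9 (0.0762), Ptgis (0.103), Sds (0.075), St6galnac2 (0.0678), Tmem88 (0.088) and Zxdc (0.162); 4 mm replicate 18 that of Cadm4 (0.0696), Eng (0.076), Gpd1l1 (0.113), Tmem88 (0.0604) and Zxdc (0.0696); 4 mm replicate 20 that of Klf9 (0.0883). Without the arrays high in brain markers 95 genes passed, and the calls of Cfi (0.0712), Eng (0.589), Folr1 (0.142), Gpd1l1 (0.227), Klf9 (0.283), Mmp9 (0.0552), Ptgis (0.117), Sds (0.0603), St6galnac2 (0.107), Tmem88 (0.122) and Zxdc (0.217) ended. Other settings gave 3 (the compared groups alone) to 393 genes (without the low-level arrays).

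By day 21 the larger defects had more Grin2d, a glutamate receptor subunit gene (2.08 ± 0.44, higher on 6 of 6 arrays, adjusted p = 0.00471), Fam229a (2.20 ± 0.47, 6 of 6), Dusp8, a phosphatase of stress-activated kinases (2.35 ± 0.53, 6 of 6), Zxdc (2.57 ± 0.58) and Cfi (1.96 ± 0.45), and Misp3, Hes7, Sema3f, Plekho2 and Fxyd5 were higher, from 1.85 to 2.34. Lower were Scg5, a protein of secretory neurons (-4.04 ± 1.20, 6 of 6, adjusted p = 0.0483), the glutamate receptor gene Gria3 (-3.07 ± 0.76, 6 of 6, adjusted p = 0.0148), the clock gene Per2 (-2.69 ± 0.66, 6 of 6, 5 of them below every 4 mm array), Galnt18 (-2.42 ± 0.59), Sf3b2 (-2.34 ± 0.55) and Tnnt2 (-2.37 ± 0.56), and Pbld1, Sfxn1, Fam136a and Camk2g were lower, from -2.29 to -2.55. The endothelial junction gene Cldn5 was lower, at -1.63 ± 0.48 and the protease gene Mmp19 at -4.46 ± 1.01 (at the floor on 5 arrays), each the only gene of its list to pass. Those lists had adjusted p = 0.401 and adjusted p = 0.745.
Brain genes were lower, with a median of -3.18, with 1 of 14 passing (4 adjusted over the list alone), the synaptic gene Snap25 (-7.72 ± 2.12, at the floor on 3 arrays), and adjusted p = 0.000752 (adjusted p = 0.233 with an estimated correlation). Bone formation genes were higher by a median of 0.83, 0 of 24 passing and 4 adjusted over the list alone, among them Mepe (3.26 ± 1.07, at the floor on 2 arrays). Tested as a list, bone formation genes had adjusted p = 0.000113 (adjusted p = 0.18 with an estimated correlation). Neutrophil genes had a median of 1.28 (0 of 16, 3 adjusted over the list alone, adjusted p = 0.00115, adjusted p = 0.0538 with an estimated correlation). Cartilage, erythroid, interferon response and T and natural killer cell genes had medians of 0.98, 1.00, 0.76 and 0.70 with 0 members passing. These had adjusted p = 0.0116, 0.00148, 0.0103 and 0.0031, and with an estimated correlation adjusted p = 0.1, 0.474, 0.581 and 0.44.
Limma called 383 genes, 86 higher and 297 lower (n = 6 against 6), of which 99, 38 higher and 61 lower, were above the floor throughout. Without the arrays high in brain markers 128 of 190 were higher, and 87 were shared with the 383. Of the named genes Camk2g (0.641), Cfi (0.0508), Cldn5 (0.543), Fam136a (0.0919), Fam229a (0.0752), Fxyd5 (0.501), Galnt18 (0.194), Gria3 (0.448), Hes7 (0.274), Mmp19 (0.106), Pbld1 (0.44), Per2 (0.233), Scg5 (0.747), Sfxn1 (0.0514), Snap25 (0.273) and Tnnt2 (0.258) were then not called (with adjusted p). Of the genes called after centring 190 of 489 were higher and after quantile normalization 1 of 8, and 6 genes passed in a fit of the compared groups alone against 705 without the low-level arrays.

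Averaged over the 7 days with equal weight, 8 mm defects had higher values of several genes of the cartilage and meninges lists. Slc5a6 was higher by 0.88 ± 0.14 (adjusted p = 0.00016), by 0.09 ± 0.29 at day 3 but 2.28 ± 0.40 at day 10. Epyc, a small proteoglycan of growth cartilage, was higher by 2.18 ± 0.35 (adjusted p = 0.00016, at the floor on 1 array). Foxc2 (1.69 ± 0.28, at the floor on 2 arrays), Foxc1 (1.37 ± 0.27, adjusted p = 0.00339), Col9a2 (1.33 ± 0.26, adjusted p = 0.00271) and the growth factor gene Bmp6 (2.25 ± 0.40, at the floor on 5 arrays) were also higher. Each had a positive sign on all 7 days, though 0 genes passed at days 1, 3 and 5. Col8a2 (0.84 ± 0.15) and Folr1 (0.93 ± 0.19) were positive on 6 of 7. The erythroid genes Klf1 and Sptb and Rbm38, Ube2o and Matn4 were higher too, from 0.80 to 1.11. Tmed9, Efcab10, Srsf11 and Rpl37 were lower, from -0.54 to -0.87. Lower in 8 mm defects were also Prr3 (-0.52 ± 0.12, adjusted p = 0.0281) and Ptms (-0.61 ± 0.14, adjusted p = 0.0226).
Of the meninges list 3 of 12 passed, all higher (5 higher and 1 lower adjusted over the list alone). The meninges list had adjusted p = 2.56e-07 (adjusted p = 0.0173 with an estimated correlation). Of the cartilage list 2 of 14 passed (3 adjusted over the list alone). The cartilage list had adjusted p = 0.0018 (adjusted p = 0.0173 with an estimated correlation). Erythroid and marrow genes had a median of 1.02 with 1 of 11 passing and 7 adjusted over the list alone (adjusted p = 2.82e-10, adjusted p = 0.0503 with an estimated correlation). BMP and TGF-beta signalling genes passed in 2 of 21 (5 higher and 1 lower adjusted over the list alone). The BMP list had adjusted p = 4.4e-06 (adjusted p = 0.0503 with an estimated correlation). Bone formation, T and natural killer cell and fibroblast genes had adjusted p = 0.0424, 0.0424 and 0.0424 with 0 members passing and medians of 0.22, 0.20 and -0.20, and with an estimated correlation adjusted p = 0.642, 0.662 and 0.728. Smooth muscle and pericyte genes had a median of -0.31, 0 of 12 passing and adjusted p = 0.0403 (adjusted p = 0.227 with an estimated correlation).
Limma called 66 genes, 56 of them higher (51 against 42 arrays), of which 26, 20 of them higher, were above the floor on every array. Centring gave 202, 172 higher, and array weights 178, 79 higher. With the rat number as a block 42 passed, 18 higher and 24 lower, and 3 were shared with the 66; at days 1 and 14 that fit rests on 1 shared number each. Without the low-level arrays 67 passed, 44 higher, with 32 shared, and over genes never at the floor 56, 41 higher, with 26 shared. The count was 37 without replicate 14 of 8 mm day 7, 39 without replicate 17 of 4 mm day 1, and 42 without replicate 14 of 8 mm day 1. Of 27 refits without 1 array, the calls of named genes ended, with their adjusted p in brackets, as follows: Efcab10 in 20 (0.0516 to 0.0977), Klf1 in 8 (0.0503 to 0.0672), Matn4 in 4 (0.0509 to 0.0796), Ptms in 1 (0.0563), Rpl37 in 7 (0.0502 to 0.0615), Sptb in 17 (0.0509 to 0.109), Srsf11 in 20 (0.0509 to 0.126), Tmed9 in 6 (0.0563 to 0.0673) and Ube2o in 3 (0.0519 to 0.0541). Without the low-level arrays the calls of Efcab10 (0.0936), Klf1 (0.0745), Prr3 (0.0661), Rbm38 (0.051), Sptb (0.0947) and Ube2o (0.0661) ended, and without those high in brain markers those of Efcab10 (0.0805), Rpl37 (0.0777), Sptb (0.0636) and Srsf11 (0.0718). In simulated data 66.7% of genes changed 2-fold were recovered for this average.

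**Figure D3:**
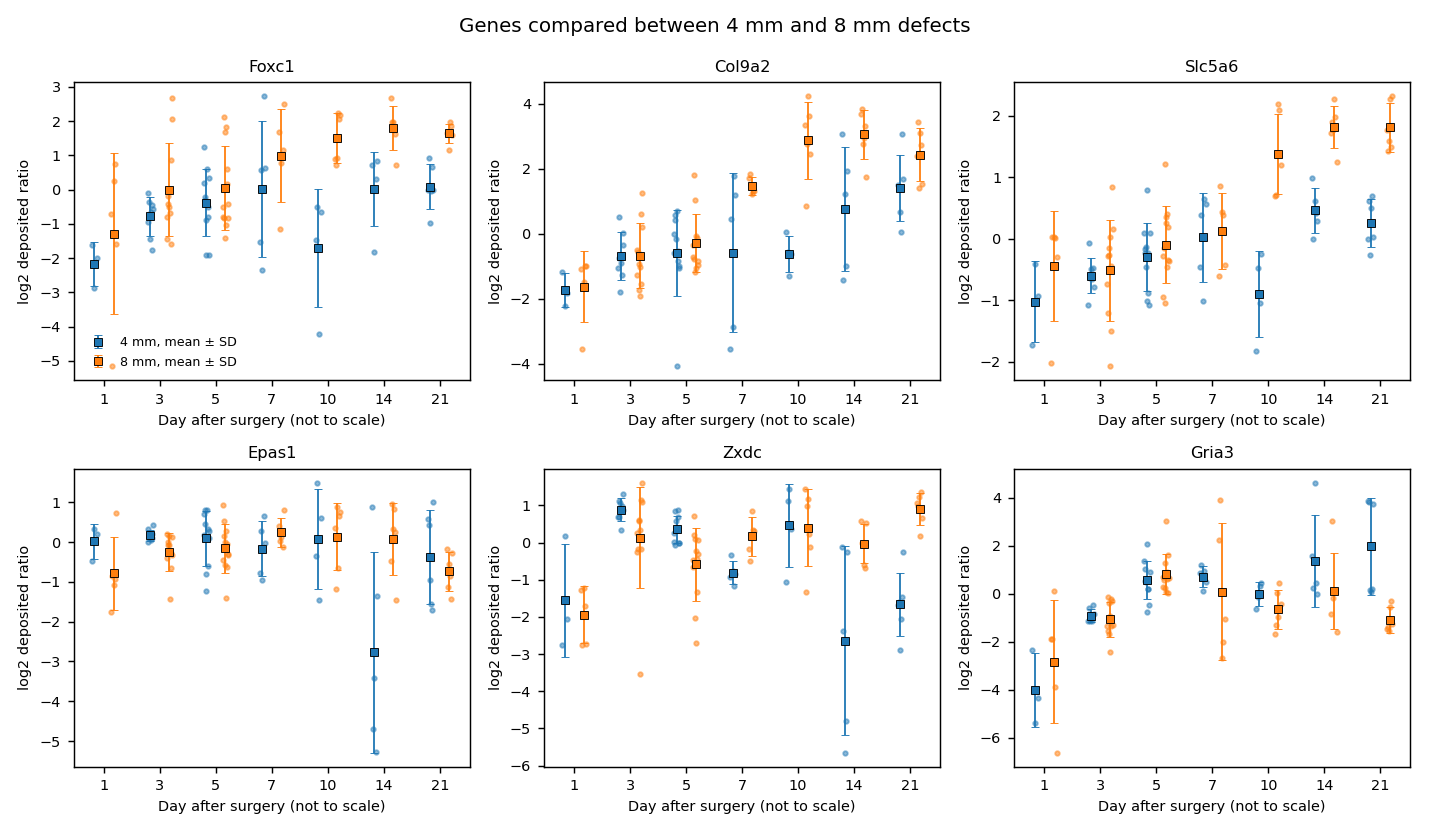
Log2 value (of the deposited ratio) of 6 genes on each of the 93 arrays by day; blue points are 4 mm and orange points 8 mm defects, offset sideways, and bars the group mean ± SD. Foxc1, Col9a2 and Slc5a6 were higher in 8 mm defects on average over the 7 days (1.37, 1.33 and 0.88), and the difference between sizes varied over the days for Slc5a6, Zxdc and Epas1.

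Whether the difference between sizes varied over the days was tested with limma's F test on the 6 interaction contrasts. Grin2d had the smallest adjusted p among the genes named above (0.00181), with differences of -0.47 ± 0.56 at day 1 and 2.08 ± 0.44 at day 21. Zxdc (adjusted p = 0.00237) was higher in 8 mm defects at day 14 (2.61 ± 0.61) and day 21 (2.57 ± 0.58), and Cfi (adjusted p = 0.00366) at day 14 (2.30 ± 0.47) and day 21 (1.96 ± 0.45). Epas1 also varied (adjusted p = 0.0392), and Slc5a6, higher at day 10 by 2.28 ± 0.40, did too (adjusted p = 0.0153). Foxc1 (adjusted p = 0.531), Foxc2 (0.24), Col9a2 (0.11) and Bmp6 (0.776) did not pass. In all 86 genes varied, and 1942 did at an unadjusted p of 0.05. The gene with the smallest adjusted p, Rad9a (adjusted p = 3.27e-08), was at the floor on 4 arrays. Of the 24 lists only the neutrophil list held a gene that passed, Lcn2. The count was 159, 175 and 176 without replicates 15, 16 and 20 of 4 mm day 14, and ran from 16 with the less variable genes left out to 349 with array weights. With the rat number as a block 184 passed and 24 were shared with the 86, and with values under 0.25 raised to 0.25 it was 84 and 36.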

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

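The tests of whole patterns, except that of cartilage genes, were chosen only after the result was seen. A single array stood far from the rest of its group, its gap to the nearest array being above the Dixon limit, in 17 of 130 group tests over 13 measures. Groups of 3 and of more than 10 arrays (4 mm day 1, 8 mm day 3 and both sizes at day 5) were not tested; among them replicate 18 of 8 mm day 3 had the lowest level of all arrays, -2.69. Chance flags about 1 in 20 groups, or 6.5 here. For the array level (median log2 value of probes never at the floor), 0.29 on replicate 13 of 4 mm day 7, -1.03 on replicate 10 of 4 mm day 10 and -0.39 on replicate 15 of 4 mm day 21 stood apart. For the percent of values at the floor, 17.15 on replicate 13 of 8 mm day 7 and 10.43 on replicate 11 of 8 mm day 10 stood apart. For the brain (neurons and glia) score, 4.29 on replicate 11 of 8 mm day 14 stood apart. For the skeletal muscle score, 0.92 on replicate 12 of 8 mm day 14 stood apart. For the meninges score, -1.10 on replicate 12 of 4 mm day 21 stood apart. For the osteoclast score, -0.66 on replicate 11 of 4 mm day 10 and 1.66 on replicate 12 of 4 mm day 21 stood apart. For the fibroblast and wound matrix score, 0.57 on replicate 15 of 4 mm day 7, -0.85 on replicate 10 of 4 mm day 10, -1.63 on replicate 17 of 4 mm day 14, -0.61 on replicate 15 of 8 mm day 14 and 0.21 on replicate 13 of 8 mm day 21 stood apart. For the neutrophil score, 2.17 on replicate 16 of 8 mm day 1 stood apart. For the cell cycle score, -0.62 on replicate 13 of 8 mm day 14 stood apart.

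The difference between sizes varied over the days, by the adjusted p of the interaction F test, for 14 of 72 genes chosen by the naming rule in the size comparisons: Grin2d (0.00181), Dusp8 (0.00194), Zxdc (0.00237), Cfi (0.00366), Cdk18 (0.0051), Acot11 (0.00619), Tmem88 (0.0112), Plekho2 (0.0139), Slc5a6 (0.0153), Cadm4 (0.0153), Usp47 (0.0376), Epas1 (0.0392), Ptgis (0.042) and Gpd1l1 (0.0422). Choosing genes for a difference at single days favours a varying difference.

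At day 21, 297 genes were lower in 8 mm than in 4 mm defects, with a median of -3.21. Brain tissue in 3 of 6 arrays of 4 mm defects stays open. Without them the median was -2.84 with all 297 below 0, but the genes were chosen with them. Still called were 50, and of 20 choices of 3 arrays this came closest to 0 (others -3.59 to -2.91). Of all calls, 128 of 190 were then higher. Array level, as a shift of whole arrays, is argued against as the whole cause, with 271 genes still called and a median of -3.04 after centring. The distribution of values over an array cannot be told apart: after quantile normalization 297 genes stayed below 0 but 7 were still called. The median difference then shrank to -2.49 (quartiles -3.29 and -1.46) while the median SE was 0.80 against 0.79. Values at the floor could account for part of it: 123 genes were still called with values under 0.25 raised to 0.25, the median was then -1.48, and 236 of the genes had a floor value on 8 mm arrays. Slower or different healing of the larger defect, which the design names, stays open and was not tested.

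Averaged over the days, 56 genes were higher in 8 mm defects. Array level is argued against, as 56 were still called after centring; after quantile normalization 29 were, with a median of 1.39 against 1.36 and a median SE of 0.34 against 0.29. More meningeal tissue under the larger trephine is a candidate explanation: 10 of 12 meninges genes had a positive difference, and the 9 not called by themselves had p = 0.0378 as a list in limma with an estimated correlation, though 3 of the genes belong to that list. More cartilage cannot be told apart, because the 12 cartilage genes not called had p = 0.11 in limma and a median of 0.19. A response to defect size in the cells themselves was not tested.

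Against day 1, 2046 genes were lower at day 21. More values at the floor on later arrays are argued against as the whole cause, since 11.2% of the 5413 genes never at the floor were called lower, against 13.6% of the others. Skeletal muscle in the early arrays is argued against as the whole cause: with a score of every other muscle gene as covariate the 2029 genes outside that list kept a median of 95.3% of their difference (lower quartile 86%), against 2.22% (upper quartile 23.7%) for the 17 muscle genes when left out of the score. A part from muscle stays open: with brain and muscle scores as covariates the median was -2.28 instead of -2.58 and 852 genes were still called, but the median SE rose from 0.72 to 0.88. Healing itself stays open and untested, as day and tissue make-up changed together.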

How the results depend on the processing

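Tests that raised low values, kept only genes above the floor, left out low-level or brain-high arrays, or used scores as covariates were chosen after the data were seen; all other settings were fixed before. The counts that moved by more than 1.5 times are given here beside those of the report, and the cause was not tested except where a setting tested fewer genes or samples. Quantile normalization gave 2 for size at day 1, 2 for size at day 3, 63 for size at day 5, 12 for size at day 10, 52 for size at day 14, 8 for size at day 21 and 33 for size by day. Centring each array on its median gave 1 for size at day 5, 65 for size at day 10, 202 for the size average and 177 for size by day. With the less variable genes left out, which could then not be called, 7987 genes were tested. The counts were 1, 6, 43 and 102 for size at days 7, 10, 14 and 21 and 18 for the size average. They were 54, 192, 597, 546, 919 and 1202 for days 3, 5, 7, 10, 14 and 21 against day 1. They were 16 for size by day and 1369 and 1797 for the 4 and 8 mm time courses. Array weights gave 37 for size at day 1, 4 for size at day 3, 20 for size at day 5, 2106 for size at day 7, 21 for size at day 10, 122 for size at day 14, 178 for the size average, 2490 for day 3 against day 1 and 349 for size by day. Fits of the compared groups alone gave 21 for size at day 1, 6 for size at day 7, 8 for size at day 10, 3 for size at day 14, 6 for size at day 21, 1120 for day 10 against day 1 and 2179 for day 14 against day 1. Raising values under 0.25 to 0.25 gave 2 for size at day 7 and 53 for size at day 14. Testing only genes above the floor on all arrays gave 108, 17, 37 and 90 for size at days 7, 10, 14 and 21. It gave 2037 and 2365 for days 14 and 21 against day 1, 33 for size by day, and 3157 and 3508 for the 4 and 8 mm time courses. Without the 7 low-level arrays the counts were 4 for size at day 1, 1 for size at day 5, 1202 for size at day 7, 393 for size at day 14, 705 for size at day 21 and 292 for size by day. Without the 8 arrays high in brain markers they were 371 for size at day 7, 95 for size at day 14, 190 for size at day 21 and 176 for size by day. Brain and muscle scores as covariates gave 116 for size at day 7 and 174 for size at day 21. An estimated correlation gave 36 for the lists.

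Leaving out 1 array at a time, in groups of 3 to 5, gave 0 to 3 for size at day 1, 37 to 98 for the size average, 629 to 1279 for day 3 against day 1, 1867 to 3531 for day 5 against day 1, 2336 to 3745 for day 7 against day 1, 1930 to 3157 for day 10 against day 1, 2475 to 3459 for day 14 against day 1, 3398 to 4165 for day 21 against day 1, 73 to 176 for size by day, 4729 to 5678 for the 4 mm time course, 6102 to 6691 for the 8 mm time course, 2 to 158 for size at day 7, 42 to 72 for size at day 10, 89 to 398 for size at day 14 and 113 to 130 for the lists. For the 284 gene results named in the report, 5965 refits left 5449 on the same side of the threshold with the same sign, 478 lost a call, 24 gained one and 14 changed sign. Those that changed sign were muscle genes with the brain and muscle scores as covariates, and none of them passed: day 7 against day 1, Actn3 0.601, Myh1 1.07 and Myl11 0.574; day 10 against day 1, Mb 0.693, Myl11 0.768, Pgam2 0.479 and Tnni2 0.501; day 14 against day 1, Mb 0.0722, Myl11 1.29 and Tnni2 0.878; day 21 against day 1, Myh1 1.63, Myl11 1.27, Pgam2 1.06 and Tnni2 0.837. The muscle score takes out what these genes share with it. Calls were lost in 20 (array weights), 25 (brain and muscle scores as covariates), 12 of 114 (the less variable genes left out), 161 (leave-one-out), 12 (mean of all probes of a gene), 5 (median centring of each array), 2 (only genes above the floor on all arrays), 66 (only the groups compared), 62 (quantile normalization), 30 (values under 0.25 raised to 0.25), 33 (without the arrays high in brain markers) and 11 (without the low-level arrays). On arrays, signal near background limits what can be seen.

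With the rat number as a replicate block the counts were 0 for size at days 3 and 5. At day 7 the count for size was 4 (2 higher and 2 lower, 3 of the report's 59 shared). At day 10 it was 65 (36 higher and 29 lower, 17 of 42 shared). At day 21 it was 420 (91 higher and 329 lower, 300 of 383 shared). For the size average it was 42 (18 higher and 24 lower, 3 of 66 shared) and for size by day 184 (24 of 86 shared). Of the lists 128 of 288 tests passed; 39 of 264 named gene calls were lost. Of 34 pairs sharing a day and a number, 13 had deviations correlated above 0.1 (median 0.0176, range -0.403 to 0.328, median of other pairs -0.00162), and 4 correlated best with their own number. Whether a number marks the same rat stays open, and on different days it marks different defects. The sizes share 8, 9, 5, 4 and 6 numbers at days 3, 5, 7, 10 and 21 but only 1 at day 1 and 1 at day 14, where the blocked fit gave no count of its own.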

Other observations

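The tests of other groupings of the arrays were all chosen only after the results were seen. Each count of genes was set against counts from other groupings of the same arrays into groups of the same sizes, 100 drawn or all where fewer, with the number of groupings giving as many genes, the real one included. At a share of groupings under 0.05, not adjusted for the 17 tests, chance could be excluded for size at day 7 (59 genes, highest other 75, 4 of 100), size at day 14 (261 genes, highest other 177, 1 of 100), size at day 21 (383 genes, highest other 448, 4 of 100), the size average (66 genes, highest other 452, 2 of 100), day 3 against day 1 (1029 genes, highest other 133, 1 of 100), day 5 against day 1 (3035 genes, highest other 3, 1 of 100), day 7 against day 1 (3419 genes, highest other 1609, 1 of 100), day 10 against day 1 (2651 genes, highest other 3387, 2 of 100), day 14 against day 1 (3350 genes, highest other 1764, 1 of 100), day 21 against day 1 (4190 genes, highest other 1253, 1 of 100), size by day (86 genes, highest other 93, 2 of 100), the 4 mm time course (5350 genes, highest other 549, 1 of 100) and the 8 mm time course (6426 genes, highest other 1140, 1 of 100). For size at day 7, size at day 21, the size average, day 10 against day 1 and size by day another grouping gave more genes than the real one, and the count for size at day 7 was 2 without replicate 13 of 8 mm day 7. Chance could not be excluded for size at day 10 (42 genes, highest other 4038, 33 of 100). With 0 genes called every grouping gives as many, so nothing about chance follows for size at day 1 (0 genes, highest other 690, 56 of 56), size at day 3 (0 genes, highest other 1, 100 of 100) and size at day 5 (0 genes, highest other 0, 100 of 100). What the groupings with more genes than the real one follow was not tested.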
